A study of Halobacterium salinarum NRC-1 with 28 samples.

How the data were processed

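Chromatin immunoprecipitation on arrays (ChIP-chip) was carried out in Halobacterium salinarum NRC-1, a salt-loving archaeon, with a c-myc-tagged form of VNG1451C, a transcription regulator of the TrmB family. Per the labels' protocols, cells grown in rich medium with 20 µg/mL mevinolin were fixed with 1.2% formaldehyde and lysed, and their DNA was sheared by sonication. Tagged protein was then immunoprecipitated, and both the immunoprecipitated DNA and the DNA of the whole-cell extract were amplified by PCR from ligated linkers and labelled with different dyes. Each immunoprecipitate was hybridised against its own extract on 2 arrays with the dyes exchanged, so the 28 arrays formed 14 dye-swap pairs, and each pair was counted as 1 replicate. The samples analysed here all carried the tag, and no mock or untagged immunoprecipitation was analysed here.

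The deposited scanner tables hold linear intensity values per spot, per the file headers: the mean of the spot, the median of the local background and the spot's peak, with no background subtraction or normalization recorded. The scanner and its software are not given in the sources used here. The arrays of 1 slide series (A) carry a brighter and a dimmer scan, and the other tables carry only the brighter scan, which was used throughout. Each array holds 21120 spots, of which 1876 belong to no tile. The remaining spots represent 4811 PCR products (tiles) of a median length of 500 bp, each spotted 4 times. The tiles comprise 4029 on the chromosome, 666 on pNRC200 and 116 on pNRC100. Coordinates are those of the array tables, and the genome build is not given in the sources used here.

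The deposited series table holds log10 values. Compared with the scanner tables, they follow the log10 ratio of the spot mean in the dye of shorter wavelength to that in the other dye without background subtraction, with a correlation over tile spots of 0.587 to 1.0 per array. Its direction was settled by this comparison, but a correlation does not depend on scale. Taken as log10 and turned to log2, the table gave means of 1.54, 1.44 and 1.35 at the 3 tiles called bound below. The scanner values gave 1.57, 1.52 and 1.35 there. Its centring and any further correction by the authors stay unknown. In replicate order, with the immunoprecipitate in channel 1 and then in channel 2, its column medians without added carbon were 0.0026, -0.0169, 0.0115, 0.0102, 0.0219, 0.012, 0.0184, -0.0299, -0.0203, -0.126, -0.006, -0.0601, -0.0038 and -0.022. In mid-log low glucose they were -0.0799, -0.0486, 0 and -0.0433, in stationary low glucose -0.0643, -0.04, -0.02 and -0.0357, in high glucose -0.0049, -0.0435, -0.0264 and -0.0437, and in glycerol 0.0232 and -0.0468. Exact zeros made up 0% to 13.2% of a column. The table was used only as an alternative.

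For each spot, the log2 ratio of the immunoprecipitate to the whole-cell extract was taken from the spot means as given. The plan had assumed background-corrected signals, which the tables do not hold. Each array was centred on the median of its tile spots, with no loess or quantile step, since a ChIP array may shift in 1 direction. Dye-swapped arrays were turned to the same direction, the spots of a tile were averaged, and the arrays of a pair were averaged. Occupancy was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a mean per group over all 14 replicates, 9 residual degrees of freedom, Benjamini-Hochberg adjustment). A tile was called bound at an adjusted p under 0.05 and a mean log2 ratio of at least 1. Groups were compared in the same way, with a tile called changed at an adjusted p under 0.05. The 5 comparisons within slide series D carried slide series A against the rest as an additive term (8 residual degrees of freedom). Comparisons with the mid-log group carried no such term, because slide series and group cannot be told apart there. The lone glycerol replicate was assumed to vary like the other groups. The groups, tests, thresholds and alternatives were fixed before the data were examined, except where an item is named as chosen afterwards.

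The planned feature was the region upstream of each annotated gene. No annotation of strain NRC-1 with its gene identifiers was used here, and the gene table at hand belonged to another strain, so the tile, the planned fallback, was the feature. For the same reason the gene lists on central metabolism, cofactors, respiration, light-driven proteins and repeated genes, the gene-body and wider-window alternatives and the locus of VNG1451C itself were not analysed here. Open reading frames were predicted with Prodigal 2.6.3 on the chromosome and pNRC200, joined from the sequences in the array tables, which gave 2168 and 386 frames. They are reported without names. The named tiles were chosen by a rule fixed in advance: the 20 highest bound tiles with a ratio above 0 in every replicate without added carbon, merged within 500 bp, and for each comparison the changed tiles or, where none changed, the 3 with the smallest p in each direction. A pair of tiles with an adjusted p under 0.05 and a mean under 1, and every stretch of neighbouring tiles described below, were named after their values had been seen.

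The set of tiles bound in slide series A alone was to be compared between the series D replicates with an exact two-sided permutation test. The arms of the inverted repeat known for the regulator (TACT and GAGTA, 7 or 8 bases apart) were searched on both strands of the tile sequences, with Fisher's exact test in scipy 1.17.1.

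The procedure was tested on simulated data of the same layout and 4811 tiles. With 200 enriched tiles of log2 1.5 or 3, 100% of either size were called bound without added carbon. In the simulated comparison of stationary glucose with no added carbon, 91% of the changes of log2 1.5 and 100% of those of log2 3 were called among 192 calls, of which 1 was false. For high glucose alone, 82% and 100% were called. The simulation shifted an enriched tile equally in every replicate without added carbon, with independent normal noise, and raised all tiles of slide series A by a constant. The 3 real bound tiles had SDs of 0.83 to 1.10 between replicates, and far fewer tiles than 200 were called. These shares therefore do not tell how many real changes of this size would be called.

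The alternatives planned in advance were normexp background correction with an offset of 50, loess within each array, removal of the dimmest 20% of tiles, the median of a tile's spots, each dye orientation alone, the deposited ratios and replicates of equal density averaged. Further ones were each replicate left out in turn, moderation with trend and robust settings, a log2 threshold of 0.585, each group's own replicates alone and other treatments of the slide series. Chosen after seeing the data were the dimmer scan in slide series A, array weights, scaling of replicates to a common SD, removal of 197 tiles that were over 50% repeated sequence, removal of pairs whose dye orientations correlated under 0.2, and normexp combined with loess. Replicates within a group share an OD600 in most groups and may come from 1 culture, so the p-values measure the spread between these samples, which may be partly technical. The number of arrays limits the precision.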

Results

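Genome-wide occupancy by tagged VNG1451C was measured as the log2 ratio of immunoprecipitated DNA to whole-cell extract at each tile, where 0 is the typical tile of an array. The design asks where this regulator lay on the genome and how glucose or glycerol in the medium altered that. No added carbon had 7 replicates: 1a, 1b, 2 and 3 on slide series A, at an OD600 of 1.68, 1.57, 1.50 and 1.03, and 4, 5 and 6 on slide series D, each at an OD600 of 1.049. Low glucose (0.1%) had 2 mid-log replicates, at an OD600 of 0.579 on slide series B and C, and 2 stationary replicates, at an OD600 of 1.607 on series D. High glucose (10%) had 2 replicates at an OD600 of 3.829, and glycerol (1 mL/L) had 1 replicate at an OD600 of 0.965, all on series D.

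The median spot intensity per array ran from 1893 to 15274 in the dye of shorter wavelength and from 2232 to 24570.2 in the dye of longer wavelength, over median local backgrounds of 213 to 5675 and 734 to 8099.8. The share of spots at or below background in either channel was 0.208% to 12.9% outside the glycerol arrays, where it was 19.2% and 20.9%. Spots with a saturated pixel made up 0.194% to 26.9% of an array. The dye orientations of a replicate correlated, across tiles, at 0.67, 0.74, 0.86, 0.95, 0.13, 0.78 and 0.16 in no added carbon replicates 1a, 1b, 2, 3, 4, 5 and 6. This correlation was -0.48 and 0.57 in mid-log low glucose, -0.21 and 0.18 in stationary low glucose, -0.26 and -0.25 in high glucose and 0.84 in glycerol. Between different no added carbon replicates the correlation ran from -0.12 to 0.36, with a median of 0.113 over 21 pairs. For pairs from different groups the median was 0.111 over 67 pairs, with a range of -0.19 to 0.61. Tiles are not independent replicates, so these correlations describe the arrays and are given without a p-value.

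Without added carbon, 3 single tiles passed the test for enrichment with VNG1451C. The tile at chromosome 918001 to 918500 had a mean log2 ratio of 1.57 ± 1.10 (SD, n = 7), 2.97-fold over the typical tile (limma, adjusted p = 0.0116). The tile at pNRC200 118501 to 119000 had 1.52 ± 1.10 (SD, n = 7; limma, adjusted p = 0.0161), and the tile at chromosome 519501 to 520000 had 1.35 ± 0.83 (SD, n = 7; limma, adjusted p = 0.00568). Each was above 0 in 7 of 7 replicates, and the median rank among the 4811 tiles of a replicate, counted from the highest, was 2, 3 and 3. The worst ranks were 63, 1822 and 204, and the pNRC200 tile had 0.62 (rank 303) and 0.05 (rank 1822) in replicates 4 and 6 of series D. It lies among 16 tiles whose extract signal averaged 0.33 log2 units over background, against a median of 2.18 over all tiles. The ratios dropped at the neighbouring tiles, whose means were 0.03 and 0.27 beside the first, 0.58 and 0.44 beside the second and -0.10 and 0.39 beside the third.

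The first of these tiles spans the gap between predicted open reading frames at 916872 to 918068 and 918171 to 918779, both on the minus strand, and holds the start of the former. The pNRC200 tile lies within 1 predicted frame at 118019 to 120244 on the minus strand. The tile at 519501 holds the end of a frame at 519129 to 519815 and the start of a frame at 519914 to 520705, both on the plus strand. A further pair of chromosomal tiles had adjusted p-values under 0.05 and means under 1, and was chosen after its values were seen. The tile at 262501 to 263000, with 0.96 ± 0.65 (SD, n = 7; limma, adjusted p = 0.0329), lies between divergent frames at 260291 to 262549 and 262683 to 263072 and holds both starts. Its adjusted p in limma was 0.05 or more under 15 of 29 other settings, and its mean was 0.62 with the immunoprecipitate in channel 2 alone. The tile at 255501 to 256000, with 0.83 ± 0.36 (SD, n = 7; limma, adjusted p = 0.00568), holds the start of a frame at 253914 to 255653 on the minus strand and the end of another at 255742 to 257811 on the same strand. Its adjusted p in limma was 0.05 or more under 4 of 29 other settings: 0.0618 with channel 2 alone, 0.733 with equal densities averaged, 0.0518 with the group's own replicates and 0.747 with pairs of correlated dye orientations alone.

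**Figure D1:**
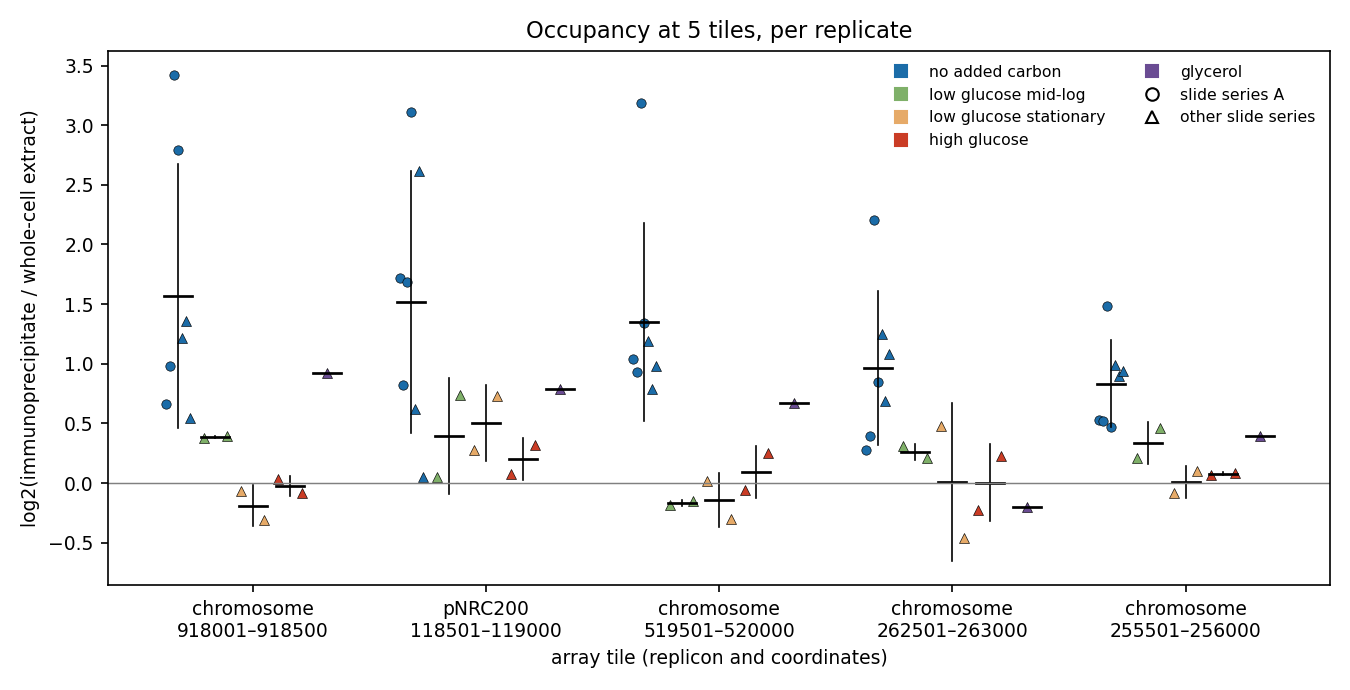
Log2 ratio of immunoprecipitate to whole-cell extract (y axis) at 5 tiles (x axis), 1 point per replicate, coloured by group, with circles for slide series A and triangles for the other slide series; horizontal bars are group means and vertical lines ± 1 SD where a group has over 1 replicate. All 7 replicates without added carbon lie above 0 at each tile, and the 4 stationary glucose replicates lie between -0.46 and 0.73.

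In the limma test, 464 tiles had an unadjusted p under 0.05 above 0 and 340 below 0 without added carbon, and the 3 bound tiles were those past both thresholds. All 3 belong to the dimmest 20% of tiles, and the count was 0 after loess within each array, where their means were 1.50, 1.27 and 1.33. The count was also 0 with replicates of equal density averaged (means 1.78, 1.69 and 1.50) or with the group's own replicates alone (the means of the full test, limma, adjusted p = 0.0858, 0.0872 and 0.0518), and 1 without replicate 5, when the tile at 519501 stayed bound. With array weights, chosen after seeing the data, the means were 0.82 at 918001, 0.59 at pNRC200 118501 and 1.04 at 519501, the last alone being called bound.

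**Figure D2:**
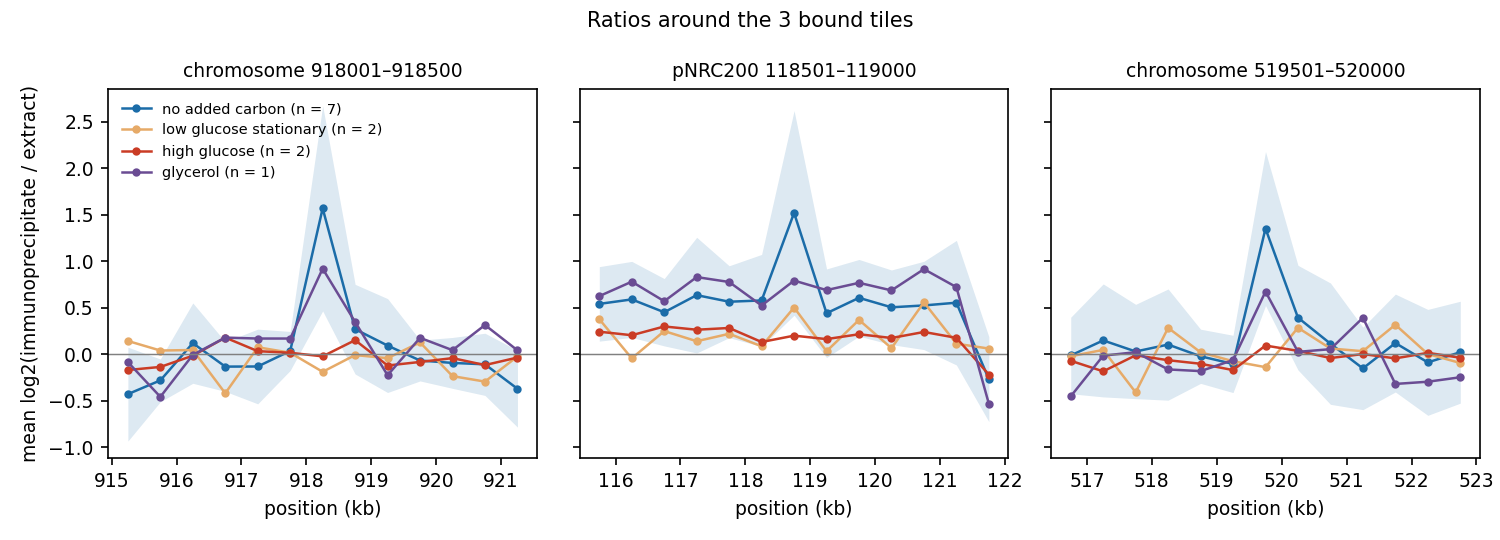
Mean log2 ratio of immunoprecipitate to whole-cell extract (y axis) against position in kb (x axis) around the 3 bound tiles, with 1 point per tile and 1 line per group; the shaded band is ± 1 SD over the 7 replicates without added carbon. Without added carbon the bound tiles reach 1.57, 1.52 and 1.35, and the tiles next to that on pNRC200 have 0.58 and 0.44.

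With carbon added, no tile was called bound in any group, but these groups had 2 replicates or 1, against 7 without added carbon. A mean of fewer replicates has a larger standard error, so a ratio as high as at a bound tile might be missed. The numbers of bound tiles therefore do not compare the media. Tiles with a mean of at least 1 numbered 3 without added carbon, 0 in each glucose group and 43 in the single glycerol replicate. Tiles with a mean of -1 or less numbered 0 without added carbon, 1 in mid-log low glucose, 0 in either stationary glucose group and 7 in glycerol. A mean over more replicates varies less, so these counts do not compare the media either. At chromosome 918001, pNRC200 118501 and chromosome 519501, the means over the 4 stationary glucose replicates were -0.11 ± 0.15, 0.35 ± 0.27 and -0.02 ± 0.23 (SD, n = 4). In mid-log low glucose they were 0.39 ± 0.01, 0.39 ± 0.49 and -0.17 ± 0.02 (SD, n = 2). The single glycerol replicate had 0.92, 0.79 and 0.67, ranks 73, 133 and 246 from the highest. In limma, tiles with an unadjusted p under 0.05 above and below 0 numbered 189 and 128 in mid-log low glucose, 19 and 66 in stationary low glucose, 0 and 1 in high glucose and 275 and 197 in glycerol. In mid-log low glucose, 175 tiles were called bound with the immunoprecipitate in channel 2 alone, but 0 with it in channel 1 alone. With channel 2 alone, 21 tiles also passed the same adjusted p at a mean of -1 or less. After normexp background correction, glycerol tiles passed on both sides of 0, but the lone replicate has no spread of its own.

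The bound tiles had lower mean ratios in stationary glucose than without added carbon, but no tile of the genome passed the test of this difference. Glucose minus no added carbon within slide series D was -1.15 ± 0.48 (SE) at chromosome 918001, -0.75 ± 0.51 at pNRC200 118501, -1.01 ± 0.39 at chromosome 519501, -0.999 ± 0.369 at chromosome 262501 and -0.90 ± 0.24 at chromosome 255501 (limma, adjusted p = 0.997 for each). With series D alone in the fit, the limma adjusted p was 0.056 at chromosome 918001, 519501 and 255501, 0.562 at pNRC200 118501 and 0.539 at 262501. Normexp widened the 5 differences, in the order above, to -1.86, -1.39, -2.03, -1.71 and -1.23, with an adjusted p of 0.999 in limma. At pNRC200 118501 the direction turned without no added carbon replicate 5, to 0.0129, and with array weights, to 0.0569. The 3 series D replicates without added carbon had means of 1.04 ± 0.44, 1.10 ± 1.35, 0.98 ± 0.20, 1.01 ± 0.29 and 0.94 ± 0.04 (SD, n = 3) at these tiles. The last 2 tiles had 0.01 ± 0.43 and 0.04 ± 0.09 in stationary glucose (SD, n = 4). These tiles were picked for high values without added carbon, which by itself widens the difference. The dye orientations of the 4 stationary glucose replicates correlated across tiles at -0.21 and 0.18 in low glucose and at -0.26 and -0.25 in high glucose. Those of no added carbon replicates 4 and 6 correlated at 0.13 and 0.16, and there the chromosomal bound tiles still ranked 2 to 4.

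Over all tiles, 0 changed between stationary glucose and no added carbon, and 31 higher and 58 lower tiles had an unadjusted p under 0.05 in limma, against 240.55 expected by chance. The counts of the comparisons below were also under this number. The fit assumed 1 spread per tile for all groups, but replicates differed in spread. The SD over tiles was 0.14 and 0.15 in high glucose and 0.57 and 0.65 in no added carbon replicates 2 and 3. A count under chance is therefore no evidence that ratios were unchanged. The smallest p among tiles lower with glucose belonged to chromosome 255501, 173001 and 297001, by start position, with differences of -0.90, -0.62 and -0.81. Among higher tiles they belonged to chromosome 364501, 437501 and 313001, with 0.63, 0.70 and 0.73. With array weights, an alternative chosen after seeing the data, 3 tiles were called lower in limma: chromosome 255501 (-0.90), 262501 (-1.06) and 519501 (-1.01). The weights were 5.13 for no added carbon replicate 6 and 4.05 for each high glucose replicate. No added carbon replicates 2, 3, 4 and 5 had 0.21, 0.18, 0.54 and 0.46, so these calls lean on few replicates.

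High glucose alone and stationary low glucose alone also had lower means at the bound tiles, with 0 tiles changed in either comparison. High glucose minus no added carbon was -1.06, -0.90 and -0.89 at chromosome 918001, pNRC200 118501 and chromosome 519501, and low glucose minus no added carbon was -1.23, -0.60 and -1.12. In limma, 18 tiles had an unadjusted p under 0.05 for high glucose (smallest adjusted p 1.0) and 117 for low glucose (smallest adjusted p 0.999). For high glucose, the smallest p belonged to chromosome 255501, 173001 and 470501 among lower tiles (-0.87, -0.56 and -0.72) and to 364501, 437501 and 1052501 among higher tiles (0.67, 0.69 and 0.76). For low glucose, they belonged to chromosome 255501, 613501 and 173001 (-0.94, -0.73 and -0.69) and to 644001, 622001 and 134001 (0.84, 0.81 and 0.86). Array weights gave 3 and 2 lower tiles, as named above, without 262501 for low glucose.

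High and stationary low glucose were compared for an effect of dose, and 0 tiles changed, with 17 at an unadjusted p under 0.05 in limma. The smallest p belonged to chromosome 389501, 326501 and 827501, higher in high glucose by 0.86, 0.75 and 0.79, and to 15001, 579501 and 990001, lower at -0.56, -0.78 and -0.52. Cell density rose with the dose here, at an OD600 of 3.829 against 1.607.

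Mid-log low glucose was set against no added carbon and against stationary low glucose. At the bound tiles, mid-log minus no added carbon was -1.18 ± 0.54, -1.13 ± 0.55 and -1.52 ± 0.43 (SE) at chromosome 918001, pNRC200 118501 and chromosome 519501 (limma, adjusted p = 1.0, 1.0 and 0.820). Over the genome 0 tiles changed, and 206 had an unadjusted p under 0.05 in limma. The smallest p belonged to chromosome 159501, 374001 and 1267001, higher in mid-log by 1.11, 1.02 and 0.87, and to 1778501, 353501 and 1190501, lower at -1.16, -0.89 and -0.84. Between stationary and mid-log low glucose, 0 tiles changed in limma, and 112 had an unadjusted p under 0.05. The smallest p belonged to chromosome 1267001, 1124001 and 1319001, lower in stationary cells at -0.97, -1.30 and -0.90, and to 353501, 1472501 and 1778501, higher by 0.84, 0.78 and 0.98. Slide series, growth phase and density cannot be told apart in these comparisons. Mid-log minus no added carbon gave 1 changed tile with the immunoprecipitate in channel 1 alone and 4 with it in channel 2 alone.

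Glycerol left the ratios at the bound tiles between those of the other media, and 0 tiles changed against no added carbon. Glycerol minus no added carbon was -0.12, -0.31 and -0.31 at chromosome 918001, pNRC200 118501 and chromosome 519501. The glycerol ratio rose as tiles became dimmer (Spearman rho -0.71, across tiles). Of the 43 tiles with a glycerol ratio of at least 1, 31 were among the dimmest 20%. The 3 bound tiles are also among the dimmest 20%, so their glycerol values cannot be told apart from this trend. In limma, 40 tiles had an unadjusted p under 0.05. The smallest p belonged to chromosome 1875001, 1879501 and 1878501, higher in glycerol by 1.41, 1.08 and 1.02, and to 1881501, 179501 and 470501, lower at -1.08, -1.01 and -1.04. With array weights, 3 tiles were called higher in limma, at chromosome 1875001, 1879501 and 1879971. Glycerol had no replicate, so these counts borrow the spread of the other groups and are no test of glycerol itself. The 3 higher tiles with the smallest p lie in a stretch of 12 tiles at 1875001 to 1881000, chosen after its values were seen, with a mean of 0.90 in glycerol, -0.02 ± 0.17 (SD, n = 7) without added carbon and -0.02 ± 0.12 (SD, n = 4) in stationary glucose.

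**Figure D3:**
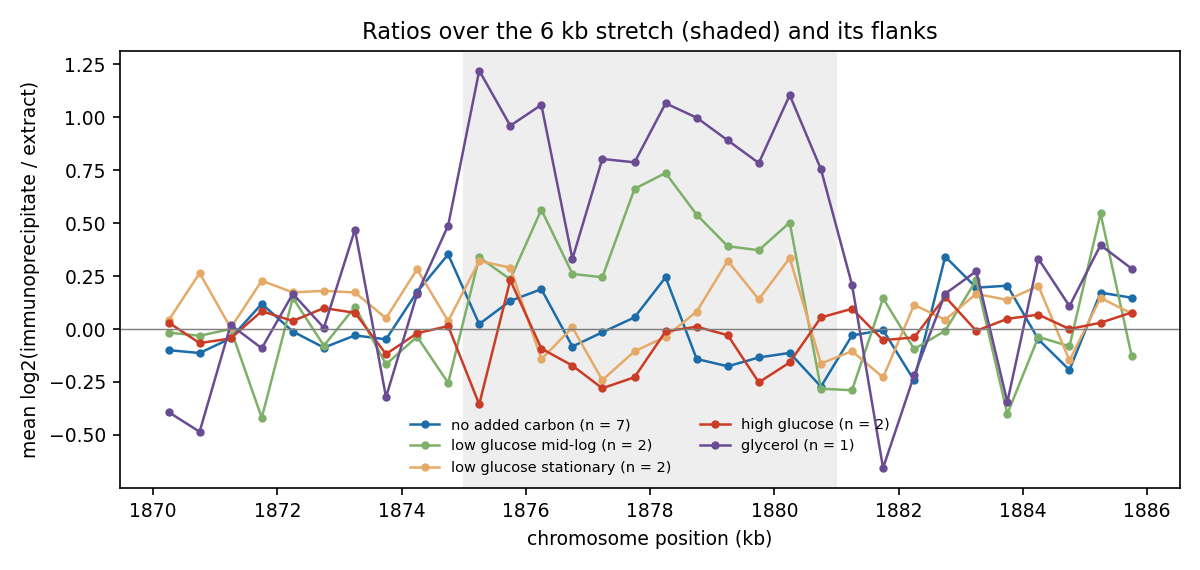
Mean log2 ratio of immunoprecipitate to whole-cell extract (y axis) against chromosome position in kb (x axis), with 1 point per tile and 1 line per group, over the 12 tiles at 1875001 to 1881000 (shaded) and their flanks; no error is drawn. The line of the single glycerol replicate averages 0.90 over the stretch, and that of no added carbon -0.02.

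To compare media at tiles chosen on other arrays, a bound set was sought in slide series A alone, but no tile passed there (limma, smallest adjusted p = 0.496). The 50 highest merged regions of series A, a set fixed beforehand in case of this, averaged 0.157 ± 0.073 (SD, n = 3) without added carbon and 0.0155 ± 0.0236 (SD, n = 4) in stationary glucose on series D. The difference was -0.14 (two-sided exact permutation test, p = 0.0571, the smallest that 35 splits allow), and -0.0616 after loess (two-sided exact permutation test, p = 0.114). The 3 tiles with a series A mean of at least 1, a set chosen after seeing the data, were the 3 bound tiles, and averaged 1.04 ± 0.53 (SD, n = 3) against 0.07 ± 0.06 (SD, n = 4) on series D. That difference was -0.97 (two-sided exact permutation test, p = 0.0571). Mid-log low glucose averaged 0.19 and 0.20 in these sets, and glycerol 0.20 and 0.79.

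The inverted repeat known for this regulator was present in 1 of the 3 bound tiles and in 8 of the other 4808 (two-sided Fisher's exact test, p = 0.0056). This rests on chromosome 918001 alone, which was not called bound after loess or without replicate 5 (limma, adjusted p = 0.162 and 0.0631), nor with equal densities averaged, the group's own replicates, array weights, pairs of correlated dye orientations alone or the dimmest 20% of tiles left out. The tile at 519501, the only one bound without replicate 5 or with array weights, lacks the repeat. Whether the repeat was first derived from these same arrays was not examined here, so the test may not be independent of them. The site lies at chromosome 918133 to 918148, upstream of the start, at 918068, of the predicted minus-strand frame. The other 8 tiles with the repeat had means of -0.32 to 0.04 without added carbon, and 2 of them, on pNRC100 and pNRC200, carry the same repeated sequence at 104928 to 104944. With the 5 tiles above the 1.5-fold threshold as the set, 1 of 5 and 8 of 4806 other tiles had the repeat (two-sided Fisher's exact test, p = 0.00932). The arms of the repeat in reversed order, a control, were in 0 of 3 bound and 21 of 4808 other tiles (two-sided Fisher's exact test, p = 1.0).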

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

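The tests of slide series, dye, brightness, immunoprecipitation in glucose and sample splits were chosen only after the result was seen. At the bound tile of chromosome 519501 to 520000, no added carbon replicate 2 had a log2 ratio of 3.18, far from the other 6, of which the next was 1.34. The gap was 0.768 of the range of the 7 values, above the 95% critical value of Dixon's test, which chance passes in about 1 of 20 groups; 5 tiles were tested in this way.

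The 3 bound tiles had higher means without added carbon than in stationary glucose, where the chromosomal tiles were near 0 and the pNRC200 tile had 0.35, though no difference passed correction. For a dye effect, the lowest mean over the 7 no added carbon arrays of 1 dye orientation was 1.33. The tiles were chosen on these arrays, so this mean does not decide. With channel 1 alone, glucose minus no added carbon was -1.41 at chromosome 918001, -1.10 at 519501 and -0.88 at the pNRC200 tile. With channel 2 alone, these differences were -0.88, -0.91 and -0.61. The direction was the same in each orientation, so 1 orientation alone did not make the difference. At the chromosomal tiles, which were also at 1 or more on series A alone, noise of dim spots is argued against by a series D mean less 1 SD above at least 98% of the 200 tiles nearest in brightness, and a slide series effect by 6 of 6 values without added carbon above every glucose value on series D. Both stay open at the pNRC200 tile, where these values were 0% and 1 of 3. Failed immunoprecipitation in glucose cannot be told apart from lower occupancy. In either stationary glucose group 0 tiles were bound, and no tile known to be bound in every medium was used here. The dye correlations were -0.21 and 0.18 in stationary low glucose and -0.26 and -0.25 in high glucose. No added carbon replicates 4 and 6, at 0.13 and 0.16, ranked the chromosomal tiles 2 to 4. They compare with the value of 0.18 but not with the negative ones, so dye correlations do not decide. The OD600 was 1.049 against 1.607 and 3.829 on series D. On series A, no added carbon replicates 1a, 1b and 2 were at 1.68, 1.57 and 1.50. They had 0.67, 0.98 and 3.42 at chromosome 918001 and 1.04, 0.93 and 3.18 at 519501. Stationary low glucose, at 1.607, had -0.07 and -0.31, and 0.02 and -0.30. This argues against cell density for low glucose at the chromosomal tiles, though across slide series and at tiles chosen partly on these replicates. Density stays open for high glucose and at the pNRC200 tile (0.82 in 1b, up to 0.73 in low glucose). A shared culture at equal density stays open too.

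For stationary glucose against no added carbon, 35 of the 35 splits of the 7 series D replicates gave as many changed tiles as the real grouping. The real count was 0 and the highest of the other splits was 0, which left no other outcome possible, and this count cannot exclude chance. At an unadjusted p under 0.05, with both glucose groups as 1 group, the real grouping had 116 tiles, 3 of the 35 splits had as many, and the highest other split had 187.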

How the results depend on the processing

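Array weights, dye correlation at 0.2, normexp with loess and the set of 3 tiles were chosen after seeing the data. The 3 tiles bound without added carbon became 0 with loess, 0 without the dimmest 20% of tiles (by construction, since all 3 are among them) and 0 with equal densities averaged (fewer samples). With the group's own replicates alone they became 0 as well, although all 7 replicates stayed. There the spread was no longer shared with the other groups, so the 3 calls rest on assuming an equal spread. Averaging equal densities also left the other groups without replicates, so the spread came from no added carbon alone in that setting too. At chromosome 918001 the SD was 1.10 without added carbon, 0.15 in stationary glucose and 0.01 in mid-log low glucose. They became 5 at a 1.5-fold threshold, 1 with array weights and 1 with only pairs whose dye orientations correlate at 0.2 or more. Leaving out 1 replicate gave 1 to 4: 1 without replicate 5, when chromosome 918001 had an adjusted p of 0.0631 and pNRC200 118501 of 0.123 in limma. The latter tile also lost its call without replicate 1a (0.0768), with channel 1 alone (0.061) and with trend and robust moderation (0.0758). Bound tiles in glycerol went from 0 to 140 with normexp, 171 with normexp and loess and 43 with array weights. In mid-log low glucose they went from 0 to 175 with the immunoprecipitate in channel 2 alone, and stayed 0 with channel 1 alone. Tiles at -1 or less also passed, 21 in mid-log with channel 2 alone and others in glycerol with normexp. These counts are therefore no list of bound sites. Changed tiles went from 0 to 3 with array weights in stationary glucose, 3 in high glucose, 2 in stationary low glucose and 3 in glycerol, and for mid-log against no added carbon to 1 and 4 with channel 1 or 2 alone. At pNRC200 118501, glucose minus no added carbon turned from -0.75 to 0.0569 with array weights and ranged from -1.27 without replicate 6 to 0.0129 without replicate 5. The shift of the 50 regions moved from -0.14 to -0.0616 with loess and to -0.97 with the 3 tiles. The motif's p was 1.0 with the arms reversed, and the motif was in no bound tile wherever chromosome 918001 lost its call. Without added carbon, 22 of 30 settings kept the bound count within 1.5 times, though with channel 1 alone and without replicate 1a chromosome 262501 (1.31 and 1.08) took the place of pNRC200 118501, and in low stationary and high glucose it was 0 under all 29 settings each. Except where the construction is named, the cause was not tested.

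Replicate numbers did not pair the samples: deviations of same-numbered replicates correlated at 0.10, 0.04 and -0.0005 across tiles. A replicate block gave 22 changed tiles for high against low glucose (18 higher, 4 lower) and 3 for stationary against mid-log low glucose. Slide series as a random block had a correlation of 0.02 and changed no call. Window, gene-body, gene-list and series A motif alternatives were not run. Signal over background was weakest in glycerol, with 19.2% and 20.9% of spots at or below background.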

Other observations

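The tests of the most enriched tile, the missing sequence, GC content, brightness trend and single replicate, and the limits of both stretches, were chosen only after the result was seen. In glycerol, 12 neighbouring tiles at chromosome 1875001 to 1881000, 6 kb in all, were raised together, with a mean log2 ratio of 0.90 ± 0.23 (SD over tiles). This was the highest of 4756 runs of 12 tiles, which is how the stretch was chosen. The mid-log low glucose replicates had 0.29 (rank 1) and 0.47 (rank 14) over the stretch, while no added carbon had -0.02 ± 0.17 (SD, n = 7) and stationary glucose -0.02 ± 0.12 (SD, n = 4). The GC content of its tiles was 54.4% to 59.4%, against a median of 68.8% on the chromosome.

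Technical sources of this stretch were weighed on the same data. A trend with brightness is argued against by the mean after loess, 1.01, although the glycerol ratio followed brightness over tiles (Spearman rho -0.71, across tiles). For low GC content, 100% of 1000 draws of tiles of equal GC content lay below the stretch, with a highest draw of 0.03. The stretch was chosen as the highest run in glycerol, so that share was nearly fixed by the choice and decides nothing. The draws themselves averaged -0.27 in glycerol, so tiles of such GC content elsewhere on the chromosome were not raised in general. A fault of the single glycerol replicate is argued against by the mid-log ranks, the lower of which was within the highest 0.294% of runs. No mock immunoprecipitation was analysed here, so unspecific recovery stays open, the genes of the stretch were not analysed here, and no biological explanation was tested.

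On pNRC200, the 16 tiles at 113501 to 121500, around the bound tile, were nearly dark. Their whole-cell extract signal was 0.33 ± 0.20 (SD over tiles) log2 units over background, against a median of 2.18 over all tiles, and their flanking tiles were 62.2% and 52.3% repeated sequence. The 15 tiles other than the bound one averaged 0.54 ± 0.06 (SD over tiles) without added carbon.

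To weigh ratios set by background alone, 1000 draws of the dimmest other tiles were compared with those 15. All of them (100%) lay below, from 0.21 to 0.43. The draws were brighter, at 0.395 against 0.285 log2 units over background, and themselves had raised ratios, with a mean of 0.32. They do not match the stretch, so background alone stays open. Whether the bound tile, also the highest of the stretch on series A alone, only shares the level of its stretch stays open, since it exceeded the others by over 3 of their SDs in 1 of 3 series D replicates without added carbon (5 of 7 with series A, on which it was chosen), lay below their mean in replicates 4 and 6 and, in glycerol, had 0.79 against 0.69. In 0 of 4735 other runs of 16 tiles was the extract as dim, the lowest being 0.98. The stretch was chosen as the longest run among the dimmest 5% of tiles, so this count was nearly fixed by the choice and decides nothing. A candidate explanation is that most cells lacked this sequence, but poor PCR products would look alike, and these cannot be told apart here. The ratio at the bound tile is then a ratio of weak signals.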
